A study of Homo sapiens with 16 samples.

How the data were processed

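RNA was measured in 16 libraries of IMR90 ER:RAS cells, in 4 groups of 4. Per the labels' protocols, total RNA was extracted with Trizol and a column kit, and libraries were made by Smart-Seq2, a full-length cDNA method, with Nextera XT indexing. Per the submitters' processing notes, the tools named were CASAVA 1.8.2, TopHat2 2.0.11 (a spliced aligner) and featureCounts 1.18.0, with the hg19 or GRCh37 genome. The annotation release, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. Smart-Seq2 does not mark strand, so overlapping and antisense genes could not be told apart. The deposited file held whole-number counts per gene for all 16 libraries, not normalized, with 62069 Ensembl gene identifiers. Every line named a gene.

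Symbols were matched by identifier for 39007 genes. The 23062 identifiers without a symbol held 0.635% of all counts. The reference genome at hand is of another build than the one the counts were made on, so no coordinates are given. The reference transcripts were used only for length and GC content, taken from the longest transcript of each gene. Replicate numbers come from the sample titles and are not shared between groups, so no paired analysis was possible.

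From the counts, edgeR 4.0.16 in R 4.3.3 was used for the main tests. Genes were kept by filterByExpr with the groups given, which left 13526. TMM factors were computed, and 1 quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to all 16 libraries with a mean per group, so that the 4 comparisons share an estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 11.9%. Levels are CPM scaled by TMM factors, as mean ± SD over 4 libraries. Folds against a group at 0 counts were computed against a floor of 3 counts over the group. Floors cover counting error only. The 95% bound of a log2 change comes from its standard error, which includes the spread between libraries.

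The 31 gene lists, with 659 memberships of which 653 matched a measured gene, were chosen before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and fry were alternatives. A list needed 5 tested members. AHCY was left out of the list tests of the hairpin comparisons.

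Named genes followed this rule. AHCY came first. Each main comparison then gave the 6 largest increases and 6 largest decreases among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3, a symbol that is not a clone name and groups whose ranges do not overlap. Each list described gave up to 4 members with the smallest adjusted p. CDKN1A, CDKN2A, CDKN2B, IL6, CXCL8, IL1A, IL1B, LMNB1, CCNA2 and MKI67 were fixed. The 5 genes per direction with the largest change shared by both hairpins, the 5 per direction moved back by both, and 4 per direction between the hairpins were added. The limits on abundance, symbol and ranges were applied to these as well, although for the first 2 sets the rule as first written did not state them. Genes outside this rule are marked in the text as chosen after their values were seen.

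Alternatives were RLE, upper-quartile and no scaling factors, DESeq2 1.42.0 with its own size factors, limma-voom, no low-count filter, a filter of 10 counts in 8 libraries, only the groups compared in the fit, a fold threshold of 1 on the log2 scale, and leaving out each library in turn. Removing each library's GC trend by a smoothing spline, as an offset in the edgeR model, was added after the data were seen. Comparisons that share the EV_4OHT libraries were set beside 20 simulations of unchanged groups and beside the 6 splits of those 4 libraries into pairs.

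The main test was tested on simulated counts. All libraries were drawn from the means of the group compared against, at their own library sizes, with 50 genes changed at each of 4 sizes. The 18 ER chaperone genes were also changed, by 1.5-fold. At 2-fold it recovered 80.9% of the changed genes tested in the senescence comparison (13041 genes run), 81.3% for shAHCY_2 (13130), 73.5% for shAHCY_4 (13147) and 79.2% between the hairpins (13066). At 1.5-fold these shares were 65.3%, 59.6%, 57.1% and 55.1%. False calls were 3.19%, 5.21%, 2.21% and 5.88% of all calls, those of the chaperone genes included. Few genes were changed in these simulations. The simulated senescence comparison called 188 genes against 7239 in the data, so its adjusted threshold was stricter and its shares do not carry over directly.

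Depth per library was 8236199 to 18235787 counts, and 11903 to 13530 genes had at least 10 counts in a library. Multidimensional scaling used the 500 most variable genes of each library pair. Replicates were checked pairwise with a chi-square test over genes with at least 20 counts in the pair, and none of the 24 pairs agreed within sampling noise, so no pair had the mark of a repeated deposit of 1 library and all 16 were kept. The test covers counting error only and does not show that the libraries came from separate cultures.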

Results

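Gene-level RNA-seq counts were collected from 16 libraries of IMR90 ER:RAS cells. IMR90 is a human lung fibroblast line, and ER:RAS is a RAS oncoprotein fused to the hormone-binding part of the oestrogen receptor, which 4-hydroxytamoxifen (4OHT) switches on. Sustained RAS signalling drives such fibroblasts into oncogene-induced senescence, a growth arrest accompanied by secretion of cytokines, growth factors and proteases, the senescence-associated secretory phenotype (SASP). The study knocked down AHCY, the enzyme that hydrolyses S-adenosylhomocysteine, the by-product of S-adenosylmethionine-dependent methylation. The 4 groups held 4 libraries each: non-senescent vector cells (EV, replicates 49 to 52), senescent vector cells given 4OHT (EV_4OHT, replicates 53 to 56), and cells given 4OHT together with the shRNA shAHCY_2 (replicates 57 to 60) or shAHCY_4 (replicates 61 to 64). The labels place the cells at day 6 and passage 15, with 4OHT at 100 nM. They do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

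Total counts per library ran from 13956130 to 18235787 in EV, from 12502278 to 15284201 in EV_4OHT, from 10066216 to 14692680 with shAHCY_2 and from 8236199 to 15144530 with shAHCY_4. Within groups, log2 CPM (counts scaled to a common library total) correlated between 0.9773 and 0.9886 across genes, and all 24 replicate pairs differed by more than sampling noise (chi-square per degree of freedom 3.15 to 35.9). The first dimension of a multidimensional scaling of the 16 libraries took 59.2% of the variance and placed the 4 EV libraries at -2.29 to -2.16 and the 12 libraries with 4OHT between 0.52 and 1.05. Replicate 59 of shAHCY_2 lay farthest from its own group, at a root mean square log2 difference of 0.499 to the other 3 libraries, against 0.318 to 0.404 for the other 15. Across genes, its deviation from the mean of all libraries also fell with GC content (Spearman's rho = -0.535), as did that of EV replicate 51 (rho = -0.266), while the other 14 libraries lay between -0.118 and 0.281. Genes are not independent replicates, so these correlations carry no test.

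AHCY (ENSG00000101444) was measured first in every library, as the target of both hairpins. Its level was 114 ± 11.3 CPM (SD, n = 4) in EV, 164 ± 8.08 in EV_4OHT, 18.5 ± 4.54 with shAHCY_2 and 14.7 ± 2.19 with shAHCY_4. All 8 hairpin libraries held 110 to 334 AHCY counts, and all 8 vector libraries held 1552 to 2583. Against EV_4OHT, AHCY fell by 3.14 ± 0.14 on the log2 scale (SE) with shAHCY_2 and fell by 3.48 ± 0.14 with shAHCY_4 (adjusted p = 3.5e-13 and 1e-13 in edgeR's quasi-likelihood test). The difference between the hairpins, 0.34 ± 0.14, did not pass the threshold (adjusted p = 0.22 in the same test), though it passed without shAHCY_2 replicate 59 (0.49) and with each library's GC trend removed (0.38). AHCY rose in senescence itself, by 0.53 ± 0.12 (adjusted p = 0.00074).

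**Figure D1:**
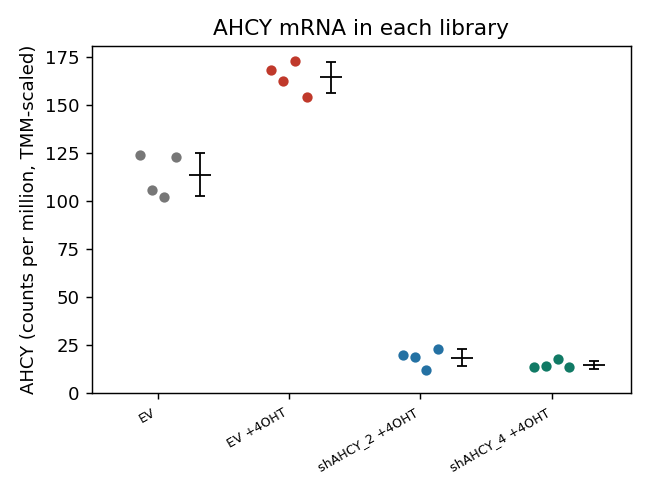
AHCY level in CPM, scaled by TMM factors, on a linear vertical axis for the 16 libraries by group (points), with the group mean and SD (black bars, n = 4). The 8 hairpin libraries lie below all 8 vector libraries, with group means of 18.5 and 14.7 against 114 and 164.

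The comparison of EV_4OHT with EV asked what RAS activation does in vector cells. No cells without the fusion were given 4OHT, so effects of 4OHT itself are not separated from it. Cytokine genes of the SASP rose: IL1B, an inflammatory cytokine, went from 0.279 ± 0.311 to 131 ± 5.68 CPM (log2 fold change 8.86 ± 0.21), and CXCL8, a neutrophil chemokine, from 3.15 ± 0.94 to 336 ± 12.2 CPM (6.73 ± 0.16). Cell cycle genes fell together, among them CCNA2, the cyclin of S phase and G2, from 84.3 ± 7.28 to 6.69 ± 0.99 CPM (-3.65 ± 0.11), and the proliferation marker MKI67 (-4.02 ± 0.21). LMNB1, the nuclear lamina protein that senescent cells lose, fell to 3.41% of its EV level (-4.84 ± 0.19). The CDK inhibitor genes CDKN2B, CDKN1A and CDKN2A rose by 3.81 ± 0.12, 1.36 ± 0.08 and 1.22 ± 0.09 on the log2 scale. Of 13526 genes tested, 3613 were higher and 3626 were lower in EV_4OHT at an adjusted p under 0.05, of which 975 and 1430 changed at least 2-fold.

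Of the 20 SASP cytokine and chemokine genes tested, 16 rose and 2 fell, with a median log2 fold change of 4.08 (camera adjusted p = 2.86e-08). IL1A, the apical interleukin of the SASP, rose by 7.18 ± 0.37, IL6 by 1.89 ± 0.25 and CXCL3 by 7.26 ± 0.25. CSF3, which encodes a granulocyte growth factor, had 0 counts in EV and 18 ± 2.3 CPM in EV_4OHT, at least 398-fold higher against a floor of 3 counts over the EV group. The list's median is the same with CSF3 at that bound, since it lies above the median either way. Of 17 SASP protease and inhibitor genes, 14 rose and 2 fell (adjusted p = 1.63e-08): the matrix metalloproteinase genes MMP3, MMP10 and MMP1 rose by 7.14 ± 0.18, 6.98 ± 0.20 and 3.63 ± 0.07, and the inhibitor gene TIMP1 by 2.67 ± 0.07. SASP growth factors and binding proteins divided into 12 higher and 9 lower of 23, with BMP2 at 5.89 ± 0.19, STC1 at 4.06 ± 0.06 and GDF15 at 3.99 ± 0.09 (adjusted p = 0.0203, and 0.0743 with an estimated correlation). TNFSF15, a TNF family ligand, and LCE1F, a late cornified envelope gene, rose by 7.62 ± 0.35 and 7.57 ± 0.22 and were, with IL1B, CXCL3, MMP3 and MMP10, the 6 largest increases under the criteria for named genes.

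Of 39 mitosis and G2/M genes, 38 fell (median -3.38, camera adjusted p = 3.06e-29), as did 43 of 44 DNA replication and G1/S genes, with 1 higher (median -1.73, adjusted p = 1.45e-22). TOP2A, the topoisomerase of mitotic chromosomes, fell by 3.63 ± 0.12, ANLN, a cytokinesis scaffold, fell by 3.52 ± 0.09, and RRM2, a ribonucleotide reductase subunit, fell by 2.88 ± 0.07 on the log2 scale. KIF20A, NDC80, DLGAP5, PBK, HMMR and CLDN11 had the 6 largest decreases under the criteria for named genes, from -4.34 ± 0.19 for KIF20A to -3.83 ± 0.22 for HMMR. CLDN11, a tight junction gene and the only one of the 6 outside the cell cycle, dropped by 4.29 ± 0.23. Of 14 nuclear lamina and HMG genes, 12 fell and 2 rose, with HMGB2 at -3.48 ± 0.12 (adjusted p = 8e-06). Matrix and contractile genes fell too: 21 of 26 fibrillar matrix genes were lower and 2 higher (adjusted p = 5.41e-08) and 11 of 13 contractile genes were lower and 1 higher (adjusted p = 2.6e-07). DCN, a collagen-binding proteoglycan, was at -3.03 ± 0.07, COL1A2 at -1.81 ± 0.08 and the smooth muscle gene TAGLN at -2.56 ± 0.08. Of 23 type I interferon response genes, 11 fell and 1 rose, with OAS3 at -2.49 ± 0.23 and IFIT2 at -2.62 ± 0.24 (adjusted p = 0.0247, and 0.237 with an estimated correlation).

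Target genes of ERK, the kinase below RAS, rose in 13 of 19 cases and fell in 2 (adjusted p = 8e-06), with the feedback phosphatase gene DUSP6 at 2.65 ± 0.08 and SPRY2 at 1.86 ± 0.09. All 13 mitochondrially encoded mRNAs rose, with MT-ND2 at 1.13 ± 0.07 (adjusted p = 1.12e-07), and the share of counts on mitochondrial genes was 5.51 ± 0.24% in EV and 6.41 ± 0.05% in EV_4OHT (two-sided exact permutation test, p = 0.0286, the smallest that 4 against 4 allows; 0.0381 adjusted over 4 comparisons). Of 20 integrated stress response genes, 15 rose and 1 fell, with the cystine transporter gene SLC7A11 at 1.64 ± 0.13 (adjusted p = 0.000101). Lysosomal genes rose in 18 of 26 cases and fell in 3, among them CTSL at 2.12 ± 0.09 and NPC1 at 2.52 ± 0.15 (adjusted p = 0.000295, and 0.22 with an estimated correlation). Of 38 cytosolic ribosomal protein genes, 14 rose and 1 fell (camera adjusted p = 0.0203, and 0.607 with an estimated correlation). Adjusted over the list alone, the counts of these lists were the same except that 2 integrated stress response genes fell.

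The p-values of single genes are from edgeR's quasi-likelihood test, and camera called 20 of the 30 lists tested, 12 of them with an estimated correlation. With library totals in place of TMM factors the median of all genes moved to -0.13, the share of called genes that were higher went from 49.9% to 38.2%, and 7 ribosomal protein genes rose and 3 fell.

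**Figure D2:**
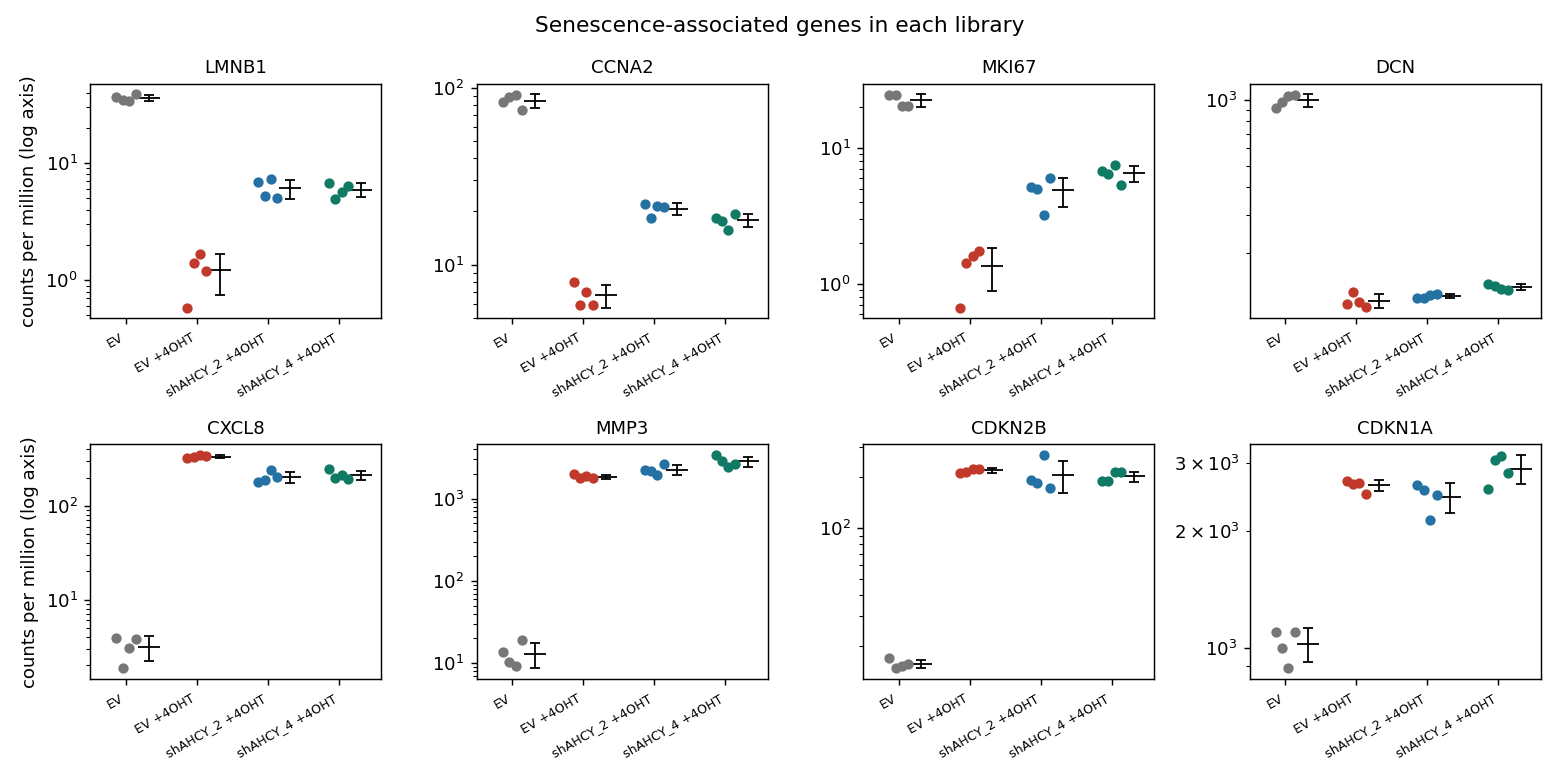
CPM (log axis) of 8 genes in the 16 libraries by group (points), with group mean and SD (black bars, n = 4). LMNB1, CCNA2 and MKI67 fell in EV_4OHT and lay between the vector groups with either hairpin, while DCN, CDKN2B and CDKN1A stayed near their EV_4OHT level.

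The comparison of shAHCY_2 with EV_4OHT asked what this hairpin does in cells with RAS switched on. Cell cycle genes were higher: PBK, a mitotic kinase, rose by 2.11 ± 0.13 on the log2 scale, NCAPG, a condensin subunit, by 2.12 ± 0.18, CDK1 by 2 ± 0.18 and MKI67 by 1.84 ± 0.23. LMNB1 rose by 2.27 ± 0.21, to 17.1% of its EV level, and CCNA2 by 1.62 ± 0.12, to 24.5%. Among SASP cytokine genes, CXCL8 had a log2 fold change of -0.73 ± 0.11 (202 ± 26.9 CPM against 336 ± 12.2), IL1B of -0.69 ± 0.11, CSF3 of -0.77 ± 0.15 and IL6 of -1.06 ± 0.24, all past the threshold. In all, 529 genes were higher and 415 lower of 13526 tested, of which 152 and 42 changed at least 2-fold.

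Of the 39 mitosis and G2/M genes, 35 rose and none fell with shAHCY_2 (38 rose adjusted over the list alone), with BUB1 at 1.65 ± 0.11 and BIRC5 at 1.70 ± 0.11 (camera adjusted p = 2.64e-56). Of the 44 DNA replication and G1/S genes, 30 rose (37 adjusted over the list alone), with RRM2 at 1.73 ± 0.07 and TK1 at 1.56 ± 0.13 (adjusted p = 4.54e-28). Of the 14 nuclear lamina and HMG genes, 9 rose (9 adjusted over the list alone), with HMGB2 at 1.22 ± 0.12 (adjusted p = 7.65e-09). The largest increase under the criteria for named genes was that of APOBEC3B, a cytidine deaminase, at 2.33 ± 0.15. CKAP2L and KIF20A, both of the mitotic spindle, rose by 1.99 ± 0.19 and 2.08 ± 0.20. CDKN1A had a log2 fold change of -0.10 ± 0.08 (adjusted p = 0.47). CDKN2B was at -0.09 ± 0.10 (adjusted p = 0.64), though it was called lower without replicate 59 (-0.25). CDKN2A fell by 0.32 ± 0.09 (adjusted p = 0.029). That last call was lost with library totals (-0.28), with the GC trend removed (-0.25), without a low-count filter and without any 1 of replicates 54, 55, 56, 57 and 60.

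Of the 20 SASP cytokine genes, 8 fell and none rose with shAHCY_2 (11 fell adjusted over the list alone; adjusted p = 0.000507, and 0.139 with an estimated correlation). IL1A had a log2 fold change of -0.55 ± 0.20 that did not pass the threshold in edgeR but did in DESeq2 (-0.56), in limma-voom (-0.58) and with the GC trend removed (-0.67). The 17 SASP proteases and inhibitors divided, with 2 higher and 5 lower (2 and 10 adjusted over the list alone): MMP1 rose by 0.27 ± 0.06, and PLAT, the tissue plasminogen activator gene, fell by 0.31 ± 0.07 (adjusted p = 0.0101, and 0.319 with an estimated correlation). Of 23 SASP growth factors and binding proteins, 6 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0224, and 0.138 with an estimated correlation). Mitochondrially encoded mRNAs fell in 11 of 13 cases (13 adjusted over the list alone), with MT-ND1 at -0.80 ± 0.08 and MT-CO1 at -0.70 ± 0.08 (adjusted p = 2.19e-15), and the mitochondrial share of counts was 4.98 ± 0.25% against 6.41 ± 0.05% (exact permutation p = 0.0286, 0.0381 adjusted). ER chaperone genes rose in 4 of 18 cases (8 adjusted over the list alone), with PDIA4 at 0.43 ± 0.07 (adjusted p = 0.000245). Of 23 type I interferon response genes, 5 rose and 1 fell (10 and 1 adjusted over the list alone), with USP18 at 0.81 ± 0.12 and IFIT1 at 1.32 ± 0.27 (adjusted p = 0.000109, and 0.138 with an estimated correlation). Contractile genes fell in 6 of 13 cases (7 adjusted over the list alone), with TAGLN at -0.34 ± 0.08 (adjusted p = 8.78e-05, and 0.139 with an estimated correlation). Of the 26 fibrillar matrix genes, 5 rose and 1 fell (9 and 3 adjusted over the list alone), with FBLN1 at 0.79 ± 0.10 (adjusted p = 0.137). Ribosomal protein genes fell in 3 of 38 cases (4 adjusted over the list alone; adjusted p = 4.32e-06, and 0.441 with an estimated correlation). Lysosomal genes fell in 6 of 26 cases and rose in 1 (13 and 1 adjusted over the list alone), with NPC1 at -0.61 ± 0.14 (adjusted p = 5.43e-05, and 0.276 with an estimated correlation). Integrated stress response genes fell in 1 of 20 cases (2 adjusted over the list alone; adjusted p = 0.286). TGF-beta target genes rose in 1 of 13 and fell in 1 (1 and 3 adjusted over the list alone; adjusted p = 0.292). The largest decreases after AHCY, under the criteria for named genes, were those of AKR1C1, an aldo-keto reductase (-1.11 ± 0.14), NEDD4L, a ubiquitin ligase (-1.03 ± 0.15), MT-TS1 (-0.98 ± 0.14), MYPN (-0.97 ± 0.16) and HMOX1, haem oxygenase 1 (-0.88 ± 0.13).

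Replicate 59, whose deviation fell with GC content, is 1 of the 4 shAHCY_2 libraries, and the log2 fold changes with shAHCY_2 fell with GC content across genes (Spearman's rho = -0.27, against 0.0104 with shAHCY_4). Leaving it out gave 823 called genes, 696 of them among the 944. Without EV_4OHT replicate 55 the count of higher genes was 349, and without EV_4OHT replicate 54 the count of lower genes was 273. The share of called genes that were higher was 56% with TMM factors, 69.8% with library totals alone and 48.65% with the GC trend removed, an alternative chosen after the data were seen.

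The same comparison for shAHCY_4 again showed cell cycle genes above their level in EV_4OHT. PLK1, the polo-like kinase of mitosis, rose by 2.17 ± 0.14 on the log2 scale, MKI67 by 2.23 ± 0.23, LMNB1 by 2.24 ± 0.21 and CCNA2 by 1.41 ± 0.12. IL6 fell by 1.88 ± 0.26, to 1.71 ± 0.69 CPM against 6.29 ± 1.49 in EV_4OHT and 1.69 ± 0.30 in EV, and CXCL8 fell by 0.66 ± 0.11, while IL1B, at -0.18 ± 0.11, did not pass the threshold (adjusted p = 0.33), though it did in DESeq2 and with only these 2 groups in the fit, at -0.18 in both. IL1A, at -0.58 ± 0.20, missed the threshold narrowly (adjusted p = 0.052) and passed under 13 alternatives, DESeq2 and limma-voom among them. Ribosomal protein genes fell in 28 of 38 cases. In all, 1025 genes were higher and 928 lower of 13526 tested, of which 189 and 139 changed at least 2-fold.

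With shAHCY_4, 36 of the 39 mitosis and G2/M genes rose and none fell (38 rose adjusted over the list alone; camera adjusted p = 2.2e-47), with BUB1B, a spindle checkpoint kinase gene, at 2.17 ± 0.18 and KIF2C at 2.14 ± 0.12. Of the 44 DNA replication and G1/S genes, 32 rose (36 adjusted over the list alone; adjusted p = 3.85e-26), with TK1 at 1.75 ± 0.13 and the licensing factor gene CDC6 at 1.68 ± 0.15. Of the 14 nuclear lamina and HMG genes, 8 rose (10 adjusted over the list alone; adjusted p = 3.61e-06). CDKN1A was at 0.14 ± 0.08 (adjusted p = 0.25), CDKN2B at -0.12 ± 0.10 (adjusted p = 0.5) and CDKN2A at -0.36 ± 0.09 (adjusted p = 0.0072). With the GC trend removed CDKN1A was called higher, also at 0.14.

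Of the 20 SASP cytokine genes, 10 fell and 1 rose with shAHCY_4 (14 and 1 adjusted over the list alone; adjusted p = 1.05e-05), among them CXCL2 at -1.20 ± 0.19 and CCL2 at -0.77 ± 0.14. The 17 SASP proteases and inhibitors divided into 5 higher and 6 lower (6 and 7 adjusted over the list alone; adjusted p = 0.445), with MMP10 at 0.64 ± 0.11, MMP1 at 0.32 ± 0.06 and ADAMTS1 at -0.83 ± 0.10. Of 23 SASP growth factors and binding proteins, 6 fell and 1 rose (6 and 3 adjusted over the list alone): the EGF family ligands EREG, AREG and NRG1 fell by 1.06 ± 0.12, 1.5 ± 0.27 and 0.78 ± 0.09 on the log2 scale (list adjusted p = 0.0317, and 0.103 with an estimated correlation, with the call also lost without any 1 of replicates 55, 56, 62 and 63). The ribosomal protein genes, 35 of which fell adjusted over the list alone, included RPL30 at -0.60 ± 0.09 and RPLP1 at -0.54 ± 0.09 (adjusted p = 6.86e-15, and 0.188 with an estimated correlation). Mitochondrially encoded mRNAs fell in 11 of 13 cases (12 adjusted over the list alone), with MT-ND1 at -0.93 ± 0.08 (adjusted p = 3.43e-12), and the mitochondrial share of counts was 4.6 ± 0.30% (exact permutation p = 0.0286, 0.0381 adjusted). Integrated stress response genes fell in 8 of 20 cases (10 adjusted over the list alone), with SLC7A11 at -0.99 ± 0.13 and the transcription factor gene ATF4 at -0.46 ± 0.08 (adjusted p = 0.000178). TGF-beta target genes fell in 5 of 13 cases and rose in 1 (7 and 2 adjusted over the list alone), with ID1 at -1.31 ± 0.13 and ID2 at -0.93 ± 0.12, both inhibitors of DNA binding (adjusted p = 0.00351). ER chaperone genes rose in 9 of 18 cases (12 adjusted over the list alone), with PDIA4 at 0.57 ± 0.07 and HSPA5 at 0.44 ± 0.06 (adjusted p = 1.04e-05). Of the 26 fibrillar matrix genes, 9 rose and 1 fell (12 and 3 adjusted over the list alone), with FBLN1 at 0.93 ± 0.10 and TNC at 0.65 ± 0.09 (adjusted p = 0.0174, and 0.345 with an estimated correlation). Of the lists described with shAHCY_2, interferon response genes rose in 2 of 23 cases and fell in 1 with shAHCY_4 (2 and 0 adjusted over the list alone; adjusted p = 0.328). Contractile genes fell in 2 of 13 cases (2 adjusted over the list alone; adjusted p = 0.215). Lysosomal genes fell in 5 of 26 and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0208, and 0.493 with an estimated correlation). The largest decreases after AHCY, under the criteria for named genes, were those of PTPRN (-1.73 ± 0.15), GPAT3 (-1.39 ± 0.13), TAGLN3 (-1.37 ± 0.09), LCE2A (-1.33 ± 0.13) and SCG5 (-1.33 ± 0.10).

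Without EV_4OHT replicate 56 the count of higher genes was 679, and with only these 2 groups in the fit the counts were 1577 higher and 1559 lower. With library totals alone the share of called genes that were higher was 67.4%, against 52.5% with TMM factors.

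**Figure D3:**
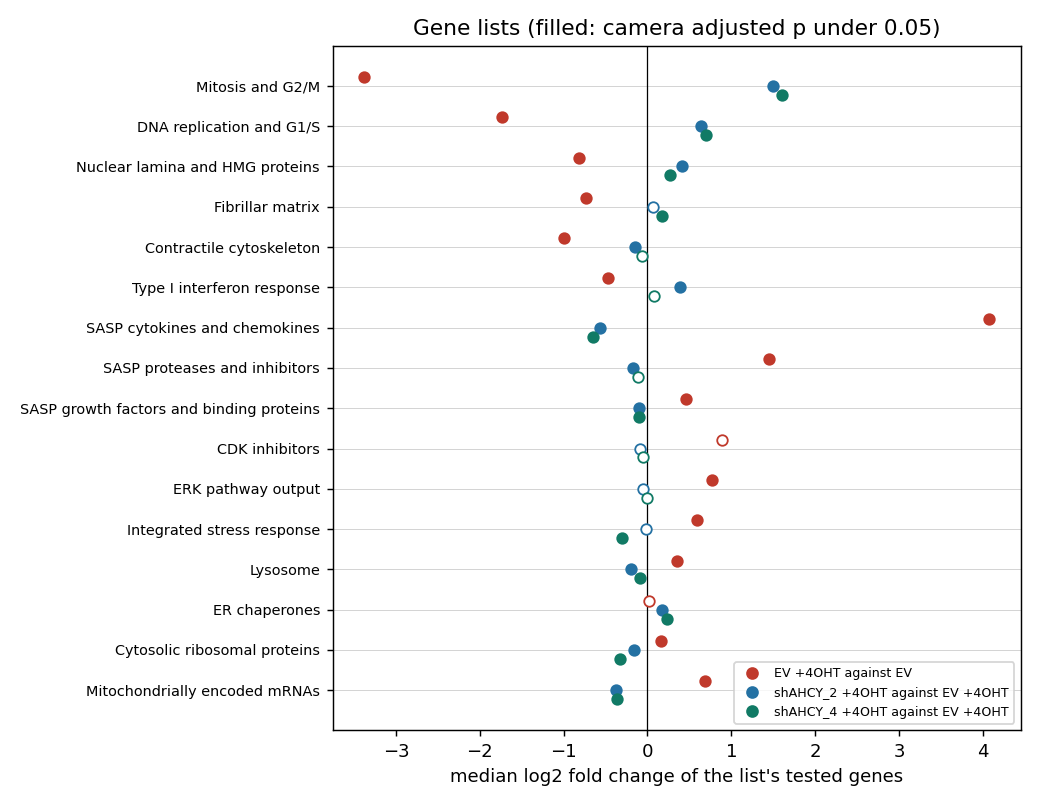
Median log2 fold change of the tested genes of 16 gene lists (horizontal axis) in the senescence comparison and with each hairpin against EV_4OHT. Filled points mark lists with a camera adjusted p under 0.05: mitosis genes had medians of -3.38 in senescence and of 1.5 and 1.60 with the hairpins, while contractile genes had medians of -1, -0.14 and -0.06.

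The hairpins were next compared for shared genes, since each can have targets of its own. Under the criteria for named genes, PBK, KIF20A, CKAP2L, APOBEC3B and BUB1B had the 5 largest rises shared by both, by 1.89 ± 0.19 or more on the log2 scale with shAHCY_2 and by 2.16 ± 0.13 or more with shAHCY_4. AHCY, AKR1C1, HMOX1, ENDOD1 and PLPP2 had the 5 largest shared falls under the same criteria, with AKR1C1 at -1.11 ± 0.14 and -1.31 ± 0.14. A total of 671 genes were called in the same direction by both hairpins, 402 higher and 269 lower, and 1 gene was called in opposite directions. It was CTSK, a collagen-degrading cathepsin gene named after its values were seen, at -0.34 ± 0.07 with shAHCY_2 and 0.21 ± 0.07 with shAHCY_4. Independent lists of these sizes would share 68.6 genes in the same direction, and 20 simulations of unchanged groups against the shared EV_4OHT libraries gave 0. Unchanged groups leave almost no genes to call, so this 0 says little. When each hairpin was compared with a different pair of EV_4OHT libraries, the 6 splits shared 267 to 299 genes, against 16 for independent lists. The covariance of the 2 sets of log2 fold changes was 0.124, against 0.0287 in the simulations and 0.0978 with split controls.

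The last comparison set the hairpin changes beside the senescence change. No hairpin group was without 4OHT, so a hairpin effect on senescence cannot be told apart from one present in any cell state. APOBEC3B fell in senescence to 7.96% of its EV level and stood at 39.9% with shAHCY_2 and 36% with shAHCY_4, and HMOX1 rose from 35.6 ± 2.79 to 176 ± 20.9 CPM and stood at 95.1 ± 18.7 and 89 ± 17.6. With shAHCY_2, 438 of the 3626 senescence-lower genes rose and 276 of the 3613 senescence-higher genes fell, and with shAHCY_4 the counts were 644 and 553. Both hairpins raised 345 senescence-lower genes, 35 of them mitosis genes and 28 DNA replication genes, and lowered 197 senescence-higher genes, AHCY among them, 10 of them mitochondrially encoded mRNAs and 6 SASP cytokine genes. Neither hairpin raised any of the 11 contractile genes that fell in senescence, while 4 of the 21 senescence-lower matrix genes rose with shAHCY_2 and 6 with shAHCY_4. DCN stood at 12.8% and 14.1% of its EV level against 12.2% in EV_4OHT. Independent lists would give 142 and 111 genes for shAHCY_2 and 275 and 248 for shAHCY_4, and 20 simulations of unchanged hairpin groups, which leave almost no genes to call, gave 0. With a different pair of EV_4OHT libraries in each comparison, the 6 splits gave 211 to 249 and 98 to 144 genes for shAHCY_2, against 56.25 and 39.1 for independent lists, and 329 to 373 and 268 to 309 for shAHCY_4, against 110.4 and 109.2. The covariance of the senescence and hairpin changes was -0.189 for shAHCY_2 (-0.0279 simulated, -0.167 with split controls) and -0.215 for shAHCY_4 (-0.029 simulated, -0.193 with split controls).

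Among genes that changed at least 2-fold in senescence, the median change with shAHCY_2 was 0.36 for the 1430 lower and -0.22 for the 975 higher genes, and with shAHCY_4 it was 0.33 and -0.28. The shared EV_4OHT libraries tend to push these medians away from 0. With a different pair of them in each comparison the means over the 6 splits were 0.29 and -0.19 with shAHCY_2 and 0.29 and -0.24 with shAHCY_4. Against EV, over all genes tested, 3314 were higher and 3188 lower with shAHCY_2, and 3439 and 3486 with shAHCY_4. These totals are not limited to genes that changed in senescence.

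**Figure D4:**
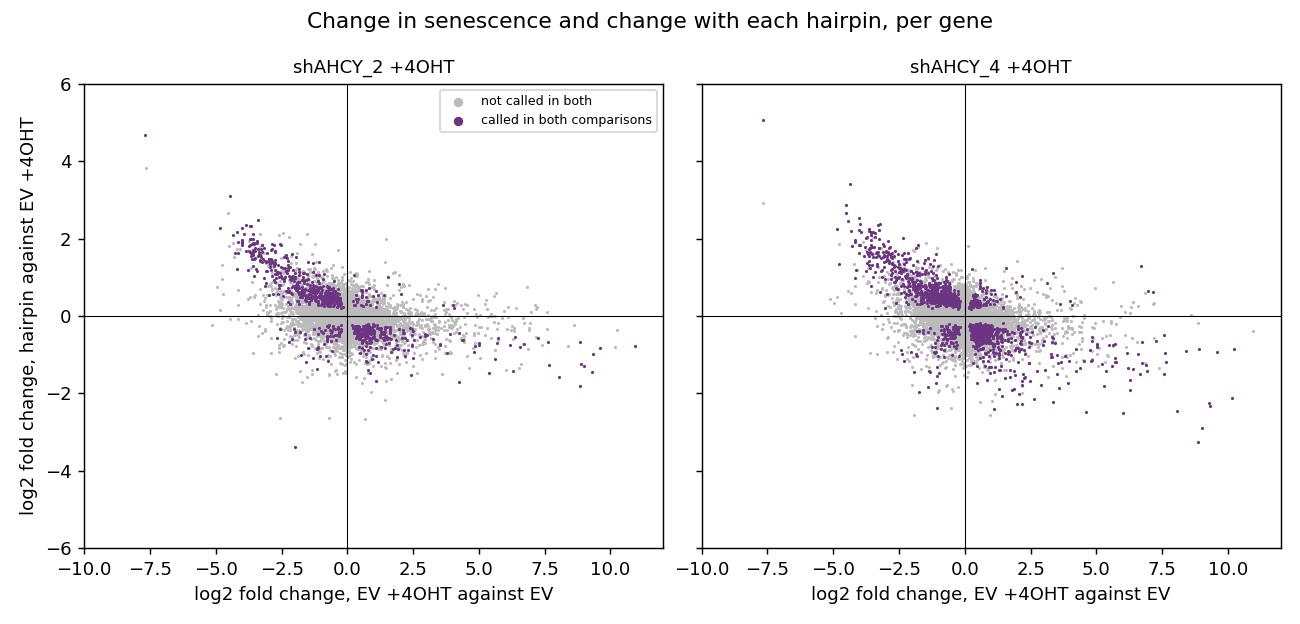
Log2 fold change of each tested gene in senescence (horizontal axis) and with a hairpin against EV_4OHT (vertical axis), AHCY and MIR30A left out, with purple points for genes called in both comparisons. Among purple points the upper left corner holds the 438 (shAHCY_2) and 644 (shAHCY_4) senescence-lower genes that rose, and the lower right corner, AHCY apart, the 276 and 553 senescence-higher genes that fell.

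The direct comparison of shAHCY_2 with shAHCY_4 tested whether their effects differed. ASPH, an aspartate hydroxylase gene, was 1310 ± 118 CPM with shAHCY_2 and 659 ± 35.6 with shAHCY_4 (log2 difference 0.99 ± 0.07), and LCOR, LCE2A and ID1 were also higher with shAHCY_2, by 1 ± 0.18, 0.97 ± 0.13 and 0.93 ± 0.13. G0S2, a lipase inhibitor gene, was lower with shAHCY_2 (-1.27 ± 0.14), as were SRGN (-1.01 ± 0.17), CCBE1 (-0.89 ± 0.11) and LRRC15 (-0.81 ± 0.17), the last not with only these 2 groups in the fit (-0.80) nor without replicate 58 or 64. In all, 95 genes were higher and 73 lower with shAHCY_2 of 13526 tested. None of the 39 mitosis or 44 DNA replication genes passed the test (adjusted over the list alone, 0 and 1, the 1 being TYMS at 0.40 ± 0.10, which passed in DESeq2, at 0.39). With the GC trend removed, 1 mitosis gene was lower and DNA replication genes were higher in 1 case, TYMS at 0.40, and lower in 2. Ribosomal protein genes were higher as a list with shAHCY_2 by a median of 0.18, although 0 of the 38 passed on their own or adjusted over the list alone (camera adjusted p = 1.83e-07, and 0.491 with an estimated correlation). Integrated stress response genes were higher in 2 of 20 cases, PSAT1 at 0.49 ± 0.08 and VLDLR at 0.94 ± 0.20 (7 adjusted over the list alone; adjusted p = 0.000467, and 0.133 with an estimated correlation). The VLDLR call was lost with only these 2 groups in the fit (0.94) and without any 1 of replicates 58, 60, 61 and 62. TGF-beta target genes were higher in 2 of 13 cases, ID1 and ID2, the latter by 0.86 ± 0.12 (5 adjusted over the list alone; adjusted p = 0.00526, and 0.133 with an estimated correlation). The mitochondrial share of counts differed by 0.373 percentage points (exact permutation p = 0.143). These counts depended on single libraries: without shAHCY_4 replicate 62 they were 41 and 28, without shAHCY_4 replicate 64 they were 38 and 37, and without EV replicate 51 they were 163 and 165. Removing each library's GC trend, an alternative chosen after that trend was seen, gave 239 higher and 376 lower genes.

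Ribosomal protein genes and mitochondrially encoded mRNAs have near-identical copies elsewhere in the genome, and AKR1C1, APOBEC3B and the LCE genes have close paralogues. The treatment of multi-mapping reads is not given in the sources used here, so the split of reads between such copies is uncertain.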

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

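The rules of this part were planned, and of the genes they were applied to, CTSK, HRAS, LINC00472 and MIR30A were named after their values were seen. Single libraries far from their group were sought among the named genes, total counts and mitochondrial shares, by dividing the gap between the highest or lowest log2 CPM and its neighbour by the group's range. Of 438 groups of 4, 22 passed the critical value at which chance gives 1 in 20, or 21.9 groups, so their number is close to that of chance.

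Replicate 59 of shAHCY_2, the library whose deviation fell with GC content, accounted for 8 of the 22. It was the highest of its group for the mitotic genes CDK1 (0.936 of the range) and HMMR (0.933), for CLDN11 (0.941) and for EREG (0.836). It was the lowest for HRAS (0.928), PDIA4 (0.925), NPC1 (0.923) and TAGLN (0.869). Replicate 60 was the lowest of the same group for CKAP2L (0.847).

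In EV_4OHT, replicate 53 was the highest for ID2 (0.931), CTSK (0.86) and ID1 (0.857), and replicate 54 was the highest for PDIA4 (0.849) and the lowest for IFIT2 (0.836). With shAHCY_4, replicate 61 was the lowest for PDIA4 (0.987) and the highest for MMP10 (0.853), and replicate 63 was the highest for AHCY (0.843). In EV, replicate 49 was the highest for TNFAIP6 (0.934) and KIF20A (0.845), and replicate 51 was the highest for LINC00472 (0.883). EV replicate 50 alone had counts of MIR30A and AREG, and its gap was the whole range (1) for both.

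The effects of the hairpins differed for 24 named genes by edgeR's quasi-likelihood test of shAHCY_2 against shAHCY_4, with log2 differences given as shAHCY_2 minus shAHCY_4. Genes higher with shAHCY_2 were AREG (1.15), LCOR (1), ASPH (0.992), LCE2A (0.968), VLDLR (0.938), ID1 (0.926), PTPRN (0.919), GPAT3 (0.891), ID2 (0.864), TAGLN3 (0.827), MIR30A (0.826), SCG5 (0.705), CCL2 (0.604), LCE1F (0.585), PSAT1 (0.493) and SPRY2 (0.395). Genes lower with shAHCY_2 were G0S2 (-1.27), SRGN (-1.01), CCBE1 (-0.891), CTSK (-0.549), MMP10 (-0.544), IL1B (-0.51), LRRC15 (-0.806) and HSPA5 (-0.258). Their adjusted p ran from 5.1e-08 for ASPH to 0.049 for HSPA5. Under at least 1 alternative the call was lost for HSPA5, AREG, CCL2, IL1B, VLDLR, SPRY2, LRRC15 and MMP10, with log2 differences for HSPA5 of -0.257 with RLE scaling and -0.205 without replicate 59. With only the 2 groups in the fit the calls of AREG, CCL2, HSPA5, LRRC15, MMP10 and VLDLR were lost, and the call of IL1B was lost without any 1 of replicates 57, 58 and 60 to 64. No explanation of these differences was tested.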

How the results depend on the processing

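Removing each library's GC trend was chosen after the results were seen. All other alternatives were planned. No call of a named gene reversed its direction under any of them, but the balance of calls moved. With the GC trend removed the share of called genes that were higher went from 56.04% to 48.65% with shAHCY_2 and from 56.55% to 38.86% between the hairpins. RLE, upper-quartile and library-total scaling, limma-voom and the filter of 10 counts in 8 libraries left all 13 counts of called genes within 1.5 times their value. No paired analysis was possible because the groups share no replicate numbers.

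DESeq2 gave 243 higher and 257 lower genes between the hairpins, and no low-count filter gave 430 and 123. With only the groups compared in the fit, shAHCY_4 had 1577 higher and 1559 lower genes, the hairpins differed in 47 and 31, and 858 senescence-higher genes were lowered by shAHCY_4. With the GC trend removed, 704 genes were lower with shAHCY_2, 1540 were higher with shAHCY_4, 239 were higher and 376 lower between the hairpins, and 476 and 841 senescence-higher genes were lowered by shAHCY_2 and shAHCY_4. These calls held 888 of the 944 genes for shAHCY_2, 1942 of 1953 for shAHCY_4 and 159 of 168 between the hairpins. The cause of these shifts was not tested.

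A fold threshold, which by construction leaves fewer genes, gave 975 higher and 1430 lower genes in senescence, 152 and 42 with shAHCY_2, 189 and 139 with shAHCY_4, and 10 and 7 between the hairpins. It left 17 senescence-higher genes lowered and 144 senescence-lower genes raised by shAHCY_2, 75 and 172 by shAHCY_4, and 149 genes shared by both hairpins. With an estimated correlation 12, 5, 8 and 0 lists were called in the 4 comparisons against 20, 13, 14 and 8 with the preset one, and fry called 5 between the hairpins. Leaving out 1 library also ended the calls of the interferon (51) and ribosomal (49 or 54) lists in senescence, of SASP growth factors with shAHCY_2 (56) and of fibrillar matrix with shAHCY_4 (63).

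Leaving out each library in turn gave 349 to 644 higher and 273 to 512 lower genes with shAHCY_2, 679 to 1267 higher and 639 to 1237 lower with shAHCY_4, and 38 to 163 higher and 28 to 165 lower between the hairpins. The lowest values came without EV_4OHT replicates 55, 54 and 56 and shAHCY_4 replicates 64 and 62, and the last comparison also moved by over 1.5 times without EV replicates 49 (120 lower), 50 (63 higher) and 51, EV_4OHT replicate 55 (58 higher), shAHCY_2 replicates 58 (44 and 44), 59 (62 higher) and 60 (57 higher), and shAHCY_4 replicate 63 (53 and 36). Among named genes, 75 of the values with a library left out lost their call and 22 gained one, against 3647 that did neither. At 1.5-fold the self-test recovered 55.1% to 65.3% of changed genes, with depth, spread and number of libraries not separated.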

Other observations

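The tests on MIR30A, on the return of cell cycle genes and on the scaling of the libraries were chosen after the results were seen. The tests on matched genes and on NRF2 targets were written before the values they measure were seen, though after the pattern itself.

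Further lists described senescence in vector cells. Glycolysis and hypoxia genes rose in 14 of 19 cases and fell in 3, with HK2, a hexokinase gene, at 2.19 ± 0.10 (camera adjusted p = 0.00466, and 0.22 with an estimated correlation). Genes of the NF-kB response outside the SASP list rose in 10 of 20 cases and fell in 3, with TNFAIP6 at 4.02 ± 0.09 and PTGS2, the inducible cyclooxygenase gene, at 5.02 ± 0.21 (adjusted p = 0.0201, and 0.22 with an estimated correlation). Immediate early genes rose in 13 of 15 cases and fell in 2 (adjusted p = 0.000295, and 0.112 with an estimated correlation), and p53 targets rose in 12 of 27 cases and fell in 2, with PLK3 at 1.91 ± 0.09 (adjusted p = 0.00538). Adjusted over the list alone these counts were the same, except that 4 genes of the NF-kB list fell. BCL2 family genes rose in 6 of 13 cases (adjusted p = 0.0138, and 0.0532 with an estimated correlation). Of the marker lists, fibroblast genes fell in 8 of 13 cases and rose in 1 (8 and 2 adjusted over the list alone; adjusted p = 0.00059), and endothelial genes rose in 4 of 6 cases and fell in 1 (the same adjusted over the list alone; adjusted p = 0.0922). Epithelial genes rose in 1 of 5 cases and fell in 2 (1 and 3 adjusted over the list alone; adjusted p = 0.0922), and of 4 blood cell genes, too few for a list test, 3 rose and 1 fell.

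With shAHCY_2, 4 of the 20 genes of this NF-kB list fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.0159, and 0.319 with an estimated correlation), and with shAHCY_4 1 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.794). PTGS2 was the gene that fell with shAHCY_4, by 0.80 ± 0.15, and it fell by 0.76 ± 0.15 with shAHCY_2. Cholesterol synthesis genes rose in 7 of 21 cases with shAHCY_4 (9 adjusted over the list alone), with EBP at 0.42 ± 0.08 (camera adjusted p = 0.00085, and 0.0656 with an estimated correlation), and in 3 of 21 cases with shAHCY_2 (4 adjusted over the list alone; adjusted p = 0.0955). Histone and DNA methyltransferase genes rose in 7 of 31 cases and fell in 1 with shAHCY_4 (7 and 2 adjusted over the list alone; adjusted p = 0.00858, and 0.0722 with an estimated correlation). Of 23 genes of the methionine cycle and polyamine synthesis, AHCY left out, 2 rose and 1 fell with shAHCY_2 and 2 rose and 4 fell with shAHCY_4, the same counts adjusted over the list alone (adjusted p = 0.801 and 0.372).

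The splits of the libraries bear on each count of called genes. For the senescence comparison, each hairpin against EV_4OHT and the hairpins against each other, 1 of the 35 splits, the real one, gave as many genes, and the highest other split gave 0, 1, 1 and 1 genes against 7239, 944, 1953 and 168. Senescence genes moved back numbered 714 for shAHCY_2 (highest other 0) and 1197 for shAHCY_4 (highest other 1). They are drawn from the genes called, of which no other split had more than 1, so these 2 counts add no support of their own. For genes called in the same direction by both hairpins, 1 of 100 splits drawn gave 671 and the highest other gave 0. That count is likewise drawn from the genes called and adds no support of its own. For the counts of called genes, the real split being the highest argues against a chance division of these libraries, at a share of splits under 0.05. The low counts of the other splits do not measure what chance gives, since mixing groups that differ widens the spread within them.

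MIR30A, the gene of a microRNA precursor, had 234 to 706 counts in all 8 hairpin libraries, 0 in EV_4OHT and 1 in EV, which is at least 784-fold higher with shAHCY_2 and at least 436-fold higher with shAHCY_4 against a floor of 3 counts over the EV_4OHT group. Activation of the locus itself is argued against by LINC00472, the gene that hosts MIR30A, whose log2 change had an upper 95% bound of 0.11 over both hairpins. A candidate explanation is a hairpin cassette built on the MIR30A precursor, which would need counts in every hairpin library, and the lowest was 234. The other 5 MIR30 precursors had 0 counts in all libraries. The labels do not describe the vector, and the explanation arose from these counts, so it stays a hypothesis.

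The return of cell cycle genes, taken in CPM, covered a median of 20% of the EV difference for mitosis genes with shAHCY_2 and 23.2% with shAHCY_4. In CPM it was not the largest return: the 16 SASP cytokine genes that rose at least 2-fold in senescence returned by a median of 38.5% and 37.5%. On the log2 scale the order was the other way. The whole mitosis list had medians of -3.38 in senescence and 1.5 and 1.60 with the hairpins. For the whole SASP cytokine list these were 4.08, -0.56 and -0.64. RNA or cells of the EV group in the hairpin libraries would return matrix and contractile genes alike, and their median return was -1.03% with shAHCY_2 and 2.13% with shAHCY_4, which argues against it. Weaker RAS activation could not be told apart. In CPM, the 9 ERK pathway genes that rose at least 2-fold in senescence returned by a median of 14.2% and 21.4%. For shAHCY_4 the quartiles were 1.8% and 38.1%. Shares in CPM of genes that rose and of genes that fell are not directly comparable, which limits this test. Over the whole list of 19, the median log2 change was 0.76 in senescence and -0.05 and -0.01 with the hairpins. The list tests differed. The list was not called by camera with either hairpin (adjusted p = 0.395 and 0.167). By fry it was called with shAHCY_4 (adjusted p = 0.00163), where 4 genes fell and 0 rose. With shAHCY_2, where 2 fell and 2 rose, fry did not call it (adjusted p = 0.104). HRAS, whose counts would include the fusion, rose by 0.72 ± 0.09 in senescence. Its log2 changes with the hairpins were -0.15 ± 0.09 and -0.05 ± 0.09. The reading of the test on the return of ERK genes was made stricter after its values were seen, from either hairpin to both. A lower AHCY level may be the cause, since 35 mitosis genes rose with both hairpins, but no other shRNA was among the libraries, so an effect of shRNA expression as such stays open.

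The fall of ribosomal protein and mitochondrially encoded mRNAs was set against technical trends. Ribosomal protein genes lay at a median log2 difference of -0.27 from genes matched on length, GC content and abundance with shAHCY_4. With shAHCY_2, where 3 of 38 fell, it was -0.12. Length and GC content were those of the longest annotated transcript, with a median of 1849 bases for these genes. The shAHCY_4 value argues against a bias of abundance, or of length and GC content so measured. Where the transcripts present were shorter than the longest annotated one, a length bias was not tested. Mitochondrially encoded mRNAs lay at -0.18 from their matches with shAHCY_4, the hairpin nearer to 0, and at -0.35 with shAHCY_2. Those matches were poorer (median distance 1.11 against 0.377). The matches themselves had a median of -0.18 with shAHCY_4 and -0.03 with shAHCY_2, so with shAHCY_4 part of the fall goes with these properties. The SE of the mean difference with shAHCY_4 was 0.084, taking the 13 genes as independent. With library totals in place of TMM factors the mitochondrially encoded mRNAs still had a median of -0.31 with the hairpin nearer to 0. The fall thus did not come from the TMM factors. These differed little (0.953 to 0.979 in EV_4OHT, 0.958 to 1.003 with shAHCY_2 and 0.998 to 1.012 with shAHCY_4). Leaving them out could not have moved the median to 0, so the test bears on no other effect of scaling. The ribosomal call of camera did not hold with an estimated correlation (adjusted p = 0.441 with shAHCY_2 and 0.188 with shAHCY_4), and a biological cause may remain, untested here.

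HMOX1, AKR1C1, SLC7A11 and SQSTM1 are targets of NRF2, the transcription factor of the oxidative stress response, and their lower level with the hairpins raised the hypothesis that other NRF2 targets fell as well. Of 17 others tested, chosen after the data were seen, 5 fell with shAHCY_2 and 7 with shAHCY_4, and none rose. Their median log2 changes were -0.24 and -0.23 (camera p = 5.55e-06 and 0.000216, and p = 0.0423 and 0.0891 with an estimated correlation). NQO1 had -0.34 ± 0.08 and -0.56 ± 0.08, TXN -0.40 ± 0.10 and -0.70 ± 0.10 and TXNRD1 -0.46 ± 0.11 and -0.41 ± 0.11, all past the threshold, although single libraries ended the call of TXN with shAHCY_2 (left out 54, 56, 57 or 58) and of TXNRD1 with both hairpins (53) and with shAHCY_4 (63 or 64). As a group these targets were thus lower, though with shAHCY_4 this does not hold under an estimated correlation. Each target called lower had risen in senescence, most by less than 2-fold. The 975 genes that rose at least 2-fold in senescence had median changes of -0.22 with shAHCY_2 and -0.28 with shAHCY_4. Camera set the targets against all genes, so a fall particular to NRF2 targets could not be told apart from this wider shift.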
